A study of Mus musculus with 4 samples.

How the data were processed

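Pituitary glands of mice that overexpress p25 and of wild-type littermates were measured at 14 and 40 weeks of age as 4 single-cell RNA libraries, 1 per genotype and age. Per the labels' protocols, glands were digested with papain for 5 min at 37 °C, red blood cells were lysed, 5000 to 8000 cells were aimed for in 2 independent runs, and libraries were made with the 10x Single Cell 3' v2 kit. The barcode sets differ between the ages, which 1 kit version does not account for. The labels do not say which libraries shared a run. The values in the deposited matrices are UMI counts per gene and cell barcode, whole numbers, per the file headers. Per the submitters' processing notes they were made with Cell Ranger 3.0.2 on mm10, while the file headers give version 3.0.1. The filter on barcodes is not stated. The fewest UMIs of a barcode were 500, 500, 653 and 502 (WT and p25OE at 14 weeks, WT and p25OE at 40 weeks, the order used throughout), over 31053 features. The barcode and feature files served as names only.

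The libraries held 8911, 15018, 12054 and 8125 barcodes. Barcodes with fewer than 500 detected genes (18.5%, 43.6%, 34.2% and 4.46%) or more than 20% mitochondrial UMIs (12.7%, 27.5%, 0.158% and 0.997%) were left out. The kept cells held 96.5%, 91.0%, 92.8% and 99.5% of each library's UMIs. Doublets were sought per library with Scrublet as implemented in scanpy and left out, but it marked only 2, 4, 2 and 0 cells, so doublets remain among the kept cells. An alternative that leaves out the 6% of cells with the highest doublet score was therefore added.

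Counts were normalised to 10000 per cell and log-transformed. From 2000 highly variable genes, chosen per library and combined, 30 principal components and 15 neighbours were computed, and all 4 libraries were clustered together with the Leiden algorithm at resolution 1, without integration. A cluster's score for a class was the mean level of the class's markers, each relative to its highest cluster. The cluster was named after the best class when at least 3 of the class's markers were at least 2-fold above the median of the other clusters and present in at least 10% of its cells. It stayed unnamed when a second class reached 0.5 of the best score with 3 markers of its own. It also stayed unnamed when the first of its 10 leading genes was a marker of another class, or when these held more markers of another class than of its own or at least 3 of other classes. There, a marker under 0.2 of its level in its highest cluster was read as free RNA and not counted. An erythroid name needed 500 haemoglobin UMIs per 10000. Unnamed clusters of at least 100 cells were clustered once more at resolution 0.5. The nearest class of a proliferating cell was the one whose mean profile had the highest Pearson correlation with the cell, over expressed genes outside the cell cycle lists. Of the markers, 1 is absent from the feature list.

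For gene ratios, UMIs were summed per library and class. Size factors were the median of ratios over the 4 libraries, from genes with at least 20 UMIs in each of them, so that a ratio is relative to the median gene of the class. Levels are given as scaled CPM, counts divided by the size factor and expressed as CPM of the geometric mean of the library totals. Ratios are p25OE over WT at 1 age, with exact intervals from 2 Poisson counts, and shares carry exact binomial intervals. Against 0 counts a ratio was computed with a floor of 3 counts over the library. A class entered with at least 50 cells in each library. For 21 gene lists, medians were taken over members with at least 20 UMIs in the 2 libraries compared, with intervals from 200 redraws of the counts, and set against 10000 random lists drawn from 20 bins of expression. A member counts as higher or lower from 1.5-fold on. Cells were thinned to 1000 UMIs wherever detection or cycling was compared, and cells with fewer were left out.

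The genes named are, first, the 7 hormone genes, Cdk5, Cdk5r1, Cdk5r2, Mcm2 and Mki67. To these come the 5 highest and 5 lowest ratios per age in all kept cells and in each main class, among genes with at least 50 UMIs, 20 scaled CPM and an interval beyond 1.5-fold. Within classes the 8 highest and 8 lowest genes that pass at both ages may be named, and up to 2 highest and 2 lowest members of each list. From the genes ranked by ratio, unnamed gene models, mitochondrial, ribosomal, sex-linked and haemoglobin genes were excluded. Within classes, genes under 10% of their level in their highest class were excluded from that ranking too. The genes named first and the members of lists faced neither limit, so free RNA of other cells can carry them. Pcsk2, Pax7, Malat1, Mbp and Stmn2 lie outside this rule and were chosen after their values were seen, as were Pou1f1, Nnat, Crhr1, Ghrhr and Cd74 as examples of free RNA, Xist and Tsix as the measured members of the sex-linked list, and Ccnd2 as the gene by which cells were parted.

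The markers, gene lists, filters, named-gene rule, comparisons and most alternatives were fixed before the data were examined. Several choices came later. The naming rule for clusters was revised in 4 rounds after clusters had been seen, which brought in the second clustering of unnamed cells, the rule on free RNA, the haemoglobin limit and the rules on leading genes of another class. Its first version left a cluster of WT cells at 40 weeks with somatotroph markers unnamed. Melanotroph-like cells became a main class, with and without the proliferating cells nearest to them, only after their share had been seen. The alternatives fixed beforehand were at least 200 or 1000 genes per cell, at most 10% mitochondrial UMIs, doublets kept, resolutions 0.5 and 2, each library clustered on its own, plain CPM, TMM factors, totals without the 7 hormone genes, a mean of per-cell CPM, list members with any UMI or at least 100 UMIs, no thinning, thinning to 2000 UMIs, and 3 cell cycle genes needed. The licensing ratios of other classes were set gene by gene against the melanotroph-like ones, with 2000 redraws under equal ratios, and the bound for that test was set after the differences had been seen. Besides the doublet scores, later additions were melanotroph-like cells with no UMI of the 10 cell cycle genes and the share of cells with a UMI of Pcsk2 or Pax7.

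The depth sets what the ratios can resolve, and the method was tested on simulated data. Counts of melanotroph-like cells were simulated with 2-fold and 4-fold differences planted. At 14 weeks the median found for 2-fold was a log2 ratio of 1.02, and the interval lay beyond 1.5-fold for 80% of the 2-fold and 99% of the 4-fold genes. At 40 weeks it did so for 59% and 90%. In somatotroph-like cells the shares were 71% and 98% at 14 weeks and 13% and 58% at 40 weeks, where p25OE had 72 cells. The simulation holds counting error only, and 1 library per group leaves the spread between animals unmeasured.

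Gene positions are from GENCODE M21 (GRCm38). Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors.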

Results

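Single cells were measured from the pituitary glands of mice that overexpress p25 (p25OE) and of their wild-type (WT) littermates at 14 and 40 weeks of age. p25 is a fragment of p35, the activator of the kinase Cdk5 that the gene Cdk5r1 encodes. RNA molecules were counted per cell with unique molecular identifiers (UMIs), short tags that mark each captured molecule. Each of the 4 groups was 1 library, so no difference could be set against a spread between replicates, and no p-value was computed. Intervals of shares and gene ratios are exact 95% intervals, those of list medians come from redrawn counts, and all cover counting error only. The libraries held 95242353 UMIs (WT, 14 weeks), 77275454 (p25OE, 14 weeks), 53714895 (WT, 40 weeks) and 60662506 (p25OE, 40 weeks). After filtering, 6577, 7663, 7925 and 7726 cells remained in the same order, with medians of 10778, 6335, 4938 and 6626 UMIs per cell. Cells were named by marker genes, and a name such as melanotroph-like means only that the markers of that cell type were found.

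The first comparison asked how the make-up of the gland differed between p25OE and WT at each age. Melanotroph-like cells, which carry the hormone precursor gene Pomc together with Pcsk2 and Pax7 as cells of the intermediate lobe do, made up 88.4% (87.6 to 89.1) of the p25OE cells at 40 weeks and 7.50% (6.92 to 8.10) of the WT cells. At 14 weeks the shares were 27.0% (26.0 to 28.0) and 8.82% (8.14 to 9.53). The share was thus 11.8-fold higher in p25OE at 40 weeks and 3.06-fold higher at 14 weeks. A class named proliferating, which carries mitosis genes such as Mki67 and Top2a, held 5.59% of the p25OE cells at 40 weeks and 0.0379% of the WT cells. At 14 weeks it held 1.97% and 0.228%. By expression, 432 of the 432 proliferating p25OE cells at 40 weeks lay nearest to the melanotroph-like class, against 84 of 151 at 14 weeks, where 32 lay nearest to lactotroph-like and 23 to somatotroph-like cells. The class profiles pool all libraries. The p25OE library at 40 weeks gave 6826 melanotroph-like but only 72 somatotroph-like and 81 lactotroph-like cells, so traits common to that library would also draw its cells to the melanotroph-like profile.

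The other hormone-producing classes held few p25OE cells at 40 weeks. Somatotroph-like cells, which make growth hormone, took 0.932% of the p25OE cells and 19.0% of the WT cells, and lactotroph-like cells, which make prolactin, took 1.05% and 19.8%. Corticotroph-like cells, which make Pomc in the anterior lobe, took 0.142% and 8.04%. Thyrotroph-like cells took 0.0259% and 1.36%, and gonadotroph-like cells 0.285% and 0.820%. Cells with markers of stem cells numbered 14 of 7726 in p25OE and 634 of 7925 in WT, and macrophage-like cells took 2.90% and 11.9%. T or NK cells took 0.168% and 3.23%, neutrophils 0.116% and 1.44%, B cells 0.0129% and 0.353%, endothelial cells 0.0129% and 0.151%, and mural cells or fibroblasts 0.0259% and 1.22%. At 14 weeks somatotroph-like cells took 16.7% in p25OE and 17.1% in WT, lactotroph-like cells 14.8% and 25.6%, corticotroph-like cells 11.8% and 13.0%, stem-like cells 7.73% and 8.89%, and macrophage-like cells 10.7% and 9.70%. More than 2-fold apart at that age were gonadotroph-like cells (1.72% and 0.775%), endothelial cells (1.08% and 0.213%), T or NK cells (2.14% and 5.22%) and B cells (0.0783% and 0.365%). Shares sum to 100% in each library, so a higher share of 1 class lowers all others. No cluster was named pituicyte, platelet or brain glia or neuron. A cluster of 37, 16, 24 and 2 cells in the 4 libraries held 5 of 6 pituicyte markers beside glial ones and stayed without a name. Erythroid cells numbered 0, 1, 41 and 0, and 7.40%, 2.22%, 16.7% and 0.207% of the cells stayed without a name.

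**Figure D1:**
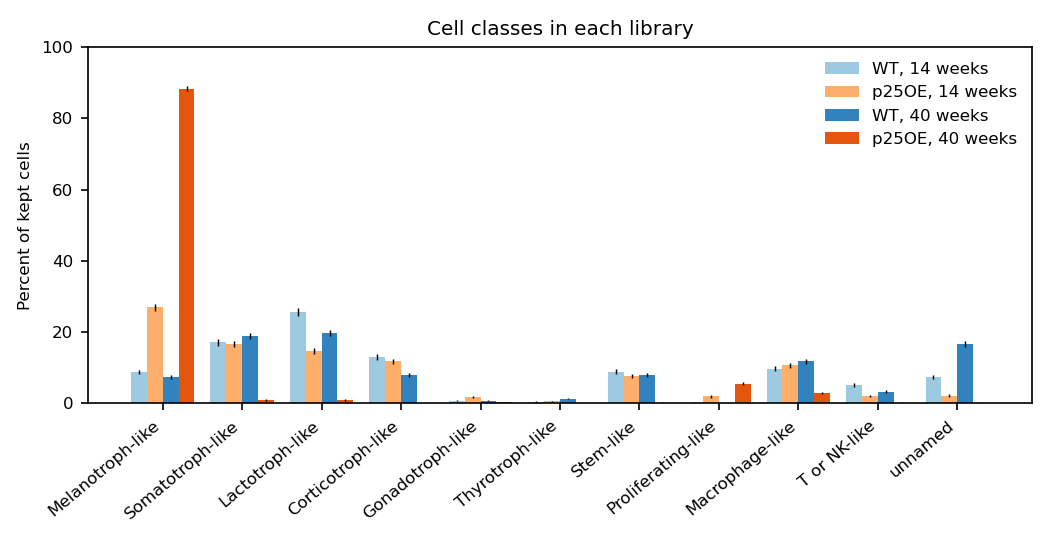
Percent of kept cells in each cell class for the 4 libraries, with exact 95% binomial intervals as error bars. Melanotroph-like cells make up 88.4% of the p25OE cells at 40 weeks and 7.50% of the WT cells.

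The melanotroph-like class was held by different clusters in different libraries. At 14 weeks WT and p25OE cells shared 1 cluster (533 and 1148 cells), p25OE had a further cluster of 549 cells (6 in WT), and a cluster with few UMIs per cell held 348 p25OE and 34 WT cells. At 40 weeks the WT cells formed a cluster of their own (594 cells), and the p25OE cells fell mainly into clusters of 3411, 1961 and 1297 cells. A single gene was also read in every cell after thinning to 1000 UMIs. Pax7, a transcription factor of intermediate-lobe cells, was detected in 13.8% of all p25OE cells at 40 weeks and 0.911% of the WT cells, and in 5.23% and 1.43% at 14 weeks. Among melanotroph-like cells it was detected in 14.7% and 6.73% at 40 weeks and in 17.6% and 14.8% at 14 weeks. Outside the melanotroph lineage, which gives the background, it was detected in 2.93% of the p25OE and 0.438% of the WT cells at 40 weeks and in 0.496% and 0.135% at 14 weeks, so these shares do not count melanotroph-like cells exactly.

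The second comparison concerned dividing cells. A cell was counted as cycling when it held at least 1 UMI of at least 2 of 10 mitosis genes after thinning to 1000 UMIs. Such cells made up 2.24% (1.91 to 2.60) of p25OE and 0.385% (0.249 to 0.567) of WT cells at 14 weeks, and 5.79% (5.27 to 6.34) and 0.190% (0.106 to 0.313) at 40 weeks. Among melanotroph-like cells together with the proliferating cells nearest to them, the shares were 4.54% and 0.348% at 14 weeks and 6.03% and 0.336% at 40 weeks. Among all other cells they were 1.34% and 0.388% at 14 weeks and 2.03% and 0.178% at 40 weeks. Macrophage-like cells gave 3.77% (1.64 to 7.30) in p25OE and 0.106% in WT at 40 weeks, on 212 and 941 cells. In those p25OE macrophage-like cells, Pcsk2, an enzyme of hormone processing, was found in 32.1%, against 82.0% of the melanotroph-like cells of that library and 11.6% of WT macrophage-like cells.

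**Figure D2:**
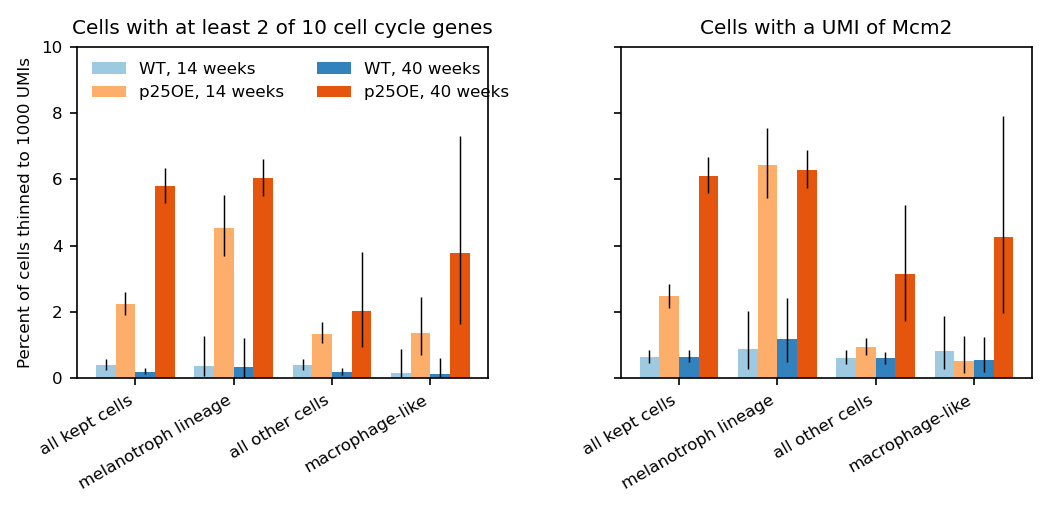
Left panel, percent of cells with at least 1 UMI of at least 2 of 10 mitosis genes. Right panel, percent of cells with a UMI of Mcm2. Both are given after thinning to 1000 UMIs, by library and group of cells, with exact 95% binomial intervals as error bars. For the mitosis genes over all kept cells, the p25OE libraries sit at 2.24% and 5.79% and the WT libraries at 0.385% and 0.190%.

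The third comparison followed genes within melanotroph-like cells, with Mcm2 first, since the study is about Mcm2 and Cdk5. Mcm2 encodes a subunit of the helicase that is loaded on replication origins. It was 4.58-fold higher in p25OE at 14 weeks (3.87 to 5.44; 12.4 scaled CPM in WT and 56.8 in p25OE) and 5.32-fold higher at 40 weeks (3.90 to 7.46; 12.0 and 63.7). After thinning, 6.25% of the p25OE cells and 0.873% of the WT cells held a UMI of Mcm2 at 14 weeks, and 6.30% and 1.18% at 40 weeks. Macrophage-like cells, used as the background, held it in 4 of 803 p25OE cells and 5 of 625 WT cells at 14 weeks. At 40 weeks they held it in 4.25% (1.96 to 7.91) of p25OE and 0.531% of WT cells, and the p25OE interval reaches the melanotroph-like share. The median depths before thinning were 17760, 7677, 7040.5 and 6791 UMIs in melanotroph-like cells and 3644, 2986, 2119 and 3342 in macrophage-like cells. Mcm2 (ENSMUSG00000002870) lies on chromosome 6 from 88883474 to 88898780 in GRCm38.

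Of the 25 measured genes for the MCM helicase and origin licensing, 19 were at least 1.5-fold higher in p25OE melanotroph-like cells at 14 weeks and 0 lower, with a median log2 ratio of 1.53 (1.32 to 1.78). At 40 weeks 18 of 24 were higher and 0 lower, with a median of 1.11 (0.81 to 1.34). Mcm3, Mcm5 and Mcm6, further subunits of the helicase, were 23.1-fold, 11.6-fold and 8.11-fold higher at 14 weeks and 21.0-fold, 7.92-fold and 13.5-fold higher at 40 weeks. S phase genes had medians of 1.56 and 1.31, with 27 of 28 higher at each age. Among them E2f1, a transcription factor that turns on replication genes, was 9.94-fold and 13.2-fold higher, and Hells, a chromatin remodeller, 17.9-fold (12.2 to 27.3) and 39.4-fold (10.9 to 326). Genes of G2 and mitosis had medians of 2.39 and 2.51, with 22 of 26 and 25 of 29 higher. Top2a, the topoisomerase that untangles chromosomes, was 26.9-fold higher at 14 weeks. At 40 weeks WT had 0 UMIs, and Top2a was 38.4-fold higher with the floor of 3 counts in place of 0. Pttg1, the securin of the anaphase, went the other way in these cells and was 1.68-fold and 2.77-fold lower. Random lists of like expression gave a median as high in 0 of 10000 draws for each of these 3 lists at both ages.

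Cdkn1a, which encodes the kinase inhibitor p21, was 8.15-fold higher at 14 weeks (6.72 to 9.98) and 8.65-fold at 40 weeks (6.09 to 12.8), and Cdkn1c (p57) 7.06-fold and 8.99-fold. Cdkn2a, which encodes p16 and p19Arf, was 7.24-fold (4.04 to 14.3) and 28.1-fold (9.59 to 136) higher. Over the list of CDK inhibitors and p53 targets, 10 of 20 genes were higher and 0 lower at 14 weeks, and 9 higher and 3 lower at 40 weeks, with medians of 0.56 and 0.54. The DNA damage response list had medians of 0.31 and 0.43. In it the kinase gene Chek1 was 7.89-fold and 4.15-fold higher and Mdc1, a scaffold at DNA breaks, 3.87-fold and 3.88-fold. Ccnd2, which encodes cyclin D2, was far lower: 498 scaled CPM in WT and 81.2 in p25OE at 14 weeks (6.14-fold lower, 5.83 to 6.46) and 465 and 9.45 at 40 weeks (49.2-fold lower, 44.5 to 54.4). The p25OE value at 40 weeks was below the 33.1 of macrophage-like cells of that library. Ccnd1, which encodes cyclin D1, was 2.07-fold and 8.81-fold lower.

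Several genes outside the cell cycle stood far apart at both ages. Pyy, which encodes peptide YY, had 0 UMIs in WT melanotroph-like cells at both ages. With a floor of 3 counts in place of 0, it was 106-fold higher in p25OE at 14 weeks and 65.5-fold at 40 weeks. After thinning, 2.16% and 5.73% of the p25OE cells held a UMI of Pyy, and 0 of 573 and 0 of 594 WT cells did, with upper bounds of 0.642% and 0.619%. In macrophage-like p25OE cells the shares were 0.125% and 1.89%. Tmprss6, a membrane protease gene, was 110-fold (30.3 to 913) and 107-fold (29.6 to 884) higher, Slc10a4, a transporter gene, 12.3-fold at both ages, and the nuclear long RNA Neat1 8.75-fold and 18.1-fold. Sp8, a zinc finger transcription factor, was 7.34-fold higher at 14 weeks and 33.1-fold at 40 weeks. Lower at both ages were the GABA receptor genes Gabra2 (2.75-fold and 3.89-fold) and Gabrb1 (2.88-fold and 3.79-fold), the neurotrophin receptor gene Ntrk2 (4.67-fold and 9.62-fold), Tmem158, Ap1s2, Olfm3, Mdga2, Fam19a1 and Gnal. Across 10055 genes with enough UMIs, the p25OE over WT log2 ratios of the 2 ages had a Pearson r of 0.479, a correlation across genes, which are not independent replicates.

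**Figure D3:**
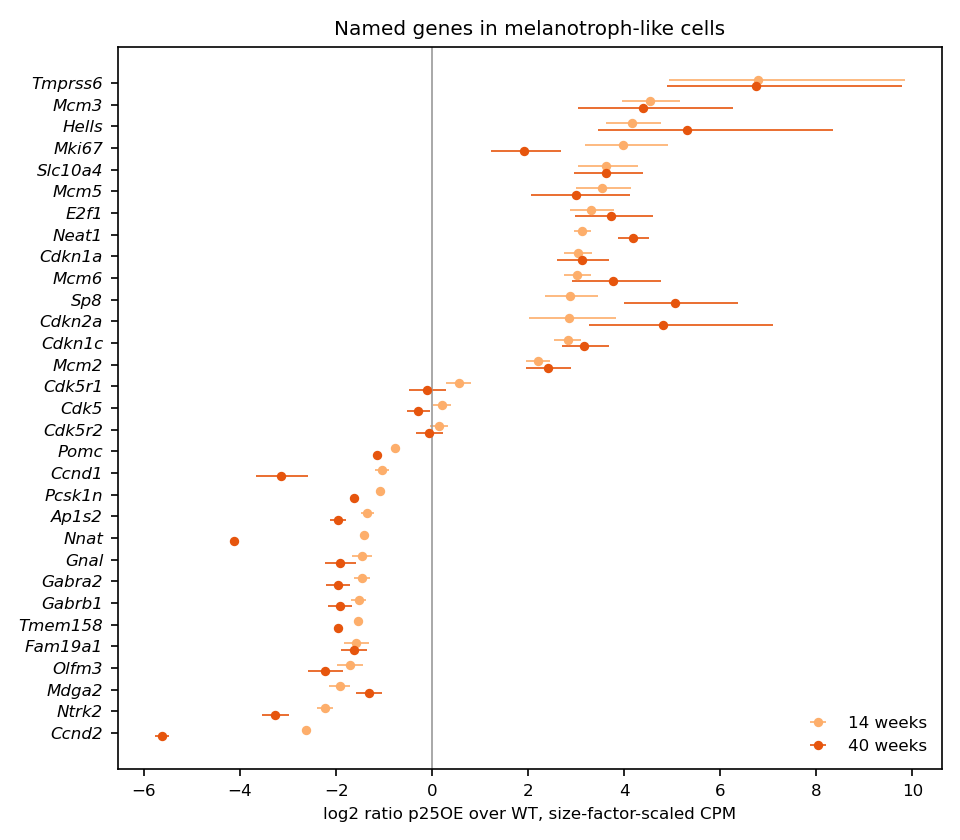
Log2 ratio of p25OE over WT in melanotroph-like cells for 31 named genes at 14 and 40 weeks, with 95% counting intervals as error bars. Of the genes shown, Ccnd2 sits lowest, at -2.62 and -5.62, and Tmprss6 highest, at 6.78 and 6.74. Pyy, with a ratio known only against a floor of 3 counts, is not shown.

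Pomc itself was lower in p25OE relative to the median gene, by 1.70-fold at 14 weeks and 2.22-fold at 40 weeks. Its median share of a melanotroph-like cell's UMIs was 20.7% in WT and 12.7% in p25OE at 14 weeks, and 23.8% and 6.91% at 40 weeks. Hormone processing and secretory granule genes had medians of -0.35 and -0.04, while the granule genes Pcsk1n and Scg2 were 2.13-fold and 1.69-fold lower at 14 weeks and 3.07-fold and 2.79-fold lower at 40 weeks. Receptors of hypothalamic signals had medians of -0.50 and -1.34, and pituitary lineage factors -0.03 and -0.04. The sign of the lineage medians and of the 40-week granule median depends on the scaling. Among the lineage factors was Isl1, a LIM homeobox factor that was 3.34-fold and 3.75-fold higher. Free RNA of other cells was present in this class. Gh, which somatotrophs make, stood at 28351 and 35856 scaled CPM in WT melanotroph-like cells and was 2.44-fold and 62.8-fold lower in p25OE, and Pou1f1, Nnat, Crhr1, Ghrhr and, at 40 weeks, Cd74, each at under 10% of its level in its highest class, were lower beside it. The MHC list (median 0.34 at 14 weeks and -0.89 at 40 weeks) and the Notch, Wnt and stem signalling list (0.59 and -0.76) share that limit.

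The remaining lists in melanotroph-like cells were as follows. Interferon response genes had a median log2 ratio of 1.29 (1.15 to 1.51) at 14 weeks, with 17 of 18 at least 1.5-fold higher, and 0.36 at 40 weeks, with 6 of 18 higher. Isg15, a ubiquitin-like protein induced by interferon, was 7.39-fold higher at 14 weeks and 1.51-fold at 40 weeks, and Ifit3 was 6.05-fold higher at 14 weeks and 2.19-fold lower at 40 weeks. Immediate early and heat shock genes, which cell dissociation also raises, had medians of 0.89 and 0.50, with Jun 7.09-fold and 2.94-fold higher and Dusp1 2.21-fold and 2.19-fold lower. The list of senescence-associated secretion had medians of 1.46 (1.05 to 1.82), with 10 of 13 genes higher and 0 lower, and 0.59 (-0.25 to 0.82), with 8 of 15 higher and 5 lower. Its members Igfbp5 and Igfbp7 are among the leading genes of stem-like, endothelial or mural clusters, so free RNA of other cells limits this list too. The chemokine gene Cxcl1 was 22.4-fold and 18.4-fold higher. Hypoxia and glycolysis genes had medians of 0.22 and 0.60, nuclear genes of oxidative phosphorylation -0.40 and -0.44, the mitochondrially encoded genes -0.01 and -0.23, the unfolded protein response -0.16 and -0.20, and pituitary tumour genes 0.04 and 0.06, with intervals that include 0. Plain CPM puts the medians of the unfolded protein response and of the mitochondrially encoded genes above 0 at both ages. The sex-linked list had 2 measured members, Xist and Tsix, with medians of -0.42 and -0.84. Haemoglobin genes, which red blood cells make, had medians of 5.57 and -12.63.

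**Figure D4:**
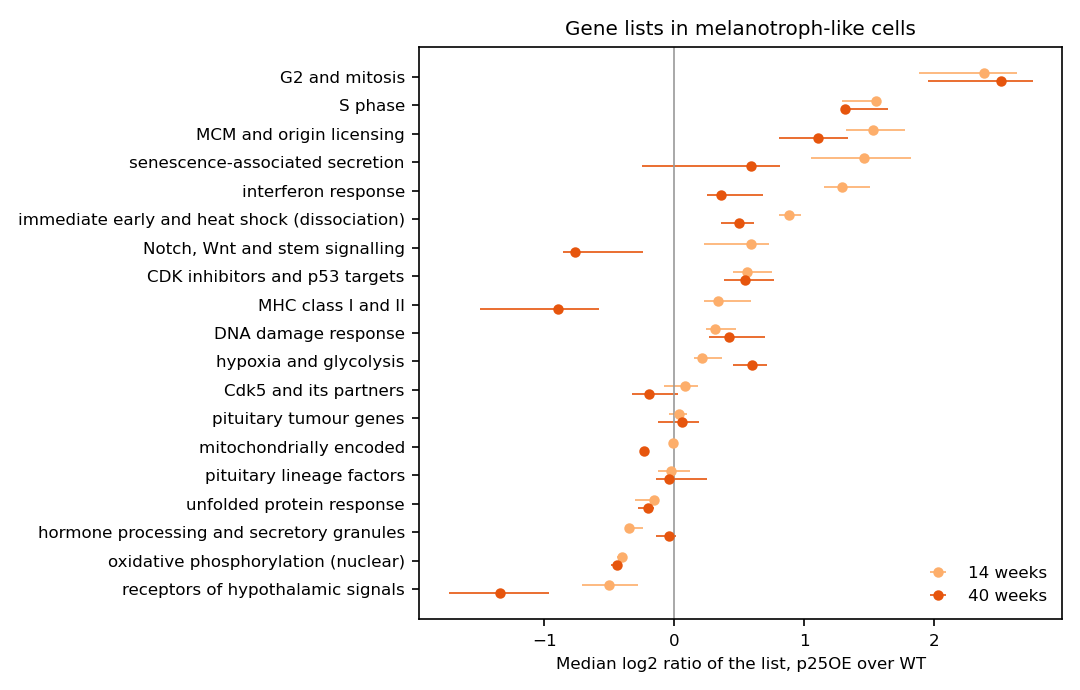
Median log2 ratio of p25OE over WT for the gene lists, without haemoglobin and the sex-linked list, in melanotroph-like cells at 14 and 40 weeks, with 95% intervals from redrawn counts. Of those shown, the replication and mitosis lists sit highest at both ages, with medians from 1.11 to 2.51, beside senescence-associated secretion (1.46) and interferon (1.29) at 14 weeks.

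Cdk5 and its activators were read in the same cells. Cdk5r1 was given first for each library, as the activator from which p25 derives: 1.22%, 2.85%, 1.01% and 2.26% of melanotroph-like cells held a UMI of it after thinning (WT and p25OE at 14 weeks, WT and p25OE at 40 weeks). Macrophage-like cells held it in 0.320%, 0.498%, 0.850% and 0 of 212 cells. Its level in melanotroph-like cells was 1.46-fold higher in p25OE at 14 weeks (1.23 to 1.75) and 1.08-fold lower at 40 weeks (0.814 to 1.40, which includes 1), the latter with a direction that depends on the scaling. The labels do not say whether transcripts of the transgene are counted as Cdk5r1, so the value does not measure the transgene. Cdk5 was 1.15-fold higher at 14 weeks (1.02 to 1.31) and 1.22-fold lower at 40 weeks (1.03 to 1.44), a direction that turns under plain CPM, and Cdk5r2, the gene of the second activator, lay at 1.10-fold and 0.960-fold of WT with intervals that include 1. The list of Cdk5 and its partners had medians of 0.09 and -0.19, with intervals that include 0, the latter above 0 under plain CPM. In all kept cells Cdk5 gave log2 ratios of 0.05 and -0.32 (above 0 under plain CPM), Cdk5r1 0.14 and 0.21, and Cdk5r2 0.35 and 0.93. Cdk5 lies on chromosome 5 from 24418241 to 24423530, and Cdk5r1 on chromosome 11 from 80477023 to 80481184.

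The fourth comparison summed all kept cells. At 40 weeks Gh was 102-fold, Prl 30.5-fold, Cga 56.0-fold, Lhb 178-fold, Fshb 67.9-fold and Tshb 793-fold lower in p25OE, and Pomc 2.36-fold higher. At 14 weeks Gh was 1.51-fold, Prl 1.73-fold, Cga 1.39-fold, Lhb 1.45-fold and Fshb 1.37-fold lower (Lhb higher as a mean of per-cell CPM), while Pomc was 1.17-fold and Tshb 1.70-fold higher. Mcm2 was 3.34-fold and 7.98-fold higher at the 2 ages, and Mki67 5.65-fold and 9.13-fold. The tissue kallikrein gene Klk1 was 13.0-fold and 19.1-fold higher. The antibody genes Igkc, Igha and Jchain, made by plasma cells, were 187-fold, 433-fold and 280-fold lower at 14 weeks and 10463-fold, 2475-fold and 627-fold lower at 40 weeks. Over all deposited barcodes, before the filters on detected genes and mitochondrial UMIs, Gh took 11.3%, 8.99%, 14.8% and 0.216% of the UMIs in the 4 libraries, and Pomc 3.29%, 4.54%, 3.81% and 12.7%.

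Somatotroph-like cells numbered 1126, 1279, 1504 and 72. At 14 weeks 1126 WT and 1277 p25OE cells shared 1 cluster, but at 40 weeks 718 and 785 WT cells lay in 2 clusters without p25OE cells, and 62 of the 72 p25OE cells in a cluster without WT cells. The dissociation list had median log2 ratios of 1.20 (1.17 to 1.33) at 14 weeks and 1.65 (1.56 to 1.85) at 40 weeks, with 19 of 21 and 16 of 20 genes higher. Interferon response genes gave 1.27 and 0.17, with 15 of 18 higher at 14 weeks, and the MHC list 0.48 and -1.40. The licensing list had medians of 0.51 (0.23 to 0.61) and 0.23 (-0.13 to 0.79). Ier2 gave 2.04 and 1.84, Egr2 3.92 and 2.83, Klf2 2.24 and 3.21, and Socs3, a feedback inhibitor of cytokine signalling, 1.73 and 3.42. Gal, which encodes the neuropeptide galanin, was lower, at -1.66 and -2.20, and Resp18, a granule protein gene, at -0.99 and -0.87. Gh was close to WT at 14 weeks (-0.09) and lower at 40 weeks (-1.15), and Mcm2 gave 0.44 at 14 weeks, with an interval that includes 0. At 40 weeks 23.6% of the 72 p25OE cells held a UMI of Pcsk2 after thinning, against 6.38% of WT cells and 82.0% of melanotroph-like p25OE cells. The log2 ratios of the 2 ages had a Pearson r of 0.552 across 2228 genes.

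Lactotroph-like cells, on 1684, 1132, 1566 and 81 cells, gave ratios of Prl of 0.08 at 14 weeks and 0.17 at 40 weeks, both below 0 as a mean of per-cell CPM. These average unlike clusters: at 40 weeks 1564 WT cells lay in 1 cluster, with 3106 Prl UMIs per 10000, and the p25OE cells mainly in clusters of 40 and 27 cells, with 4797 and 1004. At 14 weeks 181, 70 and 114 p25OE cells lay in clusters with 8, 6 and 0 WT cells. Over all libraries these clusters had medians of 2535.5, 4189 and 4247 UMIs per cell, and 6.88%, 13.4% and 15.1% mitochondrial UMIs. The cluster with 1626 WT cells of 14 weeks had 19625 UMIs and 3.91%. All 14-week ratios of this class thus average cells of unlike depth and mitochondrial share. Crhbp, which encodes the binding protein of corticotropin-releasing hormone, was lower (-0.94 and -2.69), as were Thrb, a thyroid hormone receptor gene (-0.87 and -1.34), and Hspa5, a chaperone of the endoplasmic reticulum (-0.75 and -0.77). At 14 weeks 10 of 19 genes of the unfolded protein response were lower and 0 higher, with a median of -0.67. Jun gave 0.91 and 1.02, and Lhx3, a LIM homeobox factor of the pituitary, 0.76 and 1.03. Interferon response genes were higher at 14 weeks, with 16 of 17 genes higher and a median of 1.98 (1.69 to 2.34), and gave -0.06 at 40 weeks. The licensing list had medians of -0.06 (-0.14 to 0.20) and 0.64 (-0.03 to 0.90), the latter with a sign that turned under 2 other settings, and Mcm2 gave -0.25 and 0.91 with intervals that include 0. The Pearson r between the ages was 0.264 across 3372 genes. Under 4 other filters the p25OE library held 7 to 31 lactotroph-like cells at 40 weeks, too few for a value.

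Macrophage-like cells served as a class outside the hormone lineages. Their licensing list had medians of 0.45 (0.26 to 0.74) at 14 weeks and 0.97 (0.50 to 1.21) at 40 weeks, their interferon list 0.69 and 0.17, and their dissociation list 0.66 and 0.30. Their G2 and mitosis list gave 1.89 and 3.03, the latter -0.58 with list members of at least 100 UMIs. At 40 weeks 32.1% of the p25OE macrophage-like cells held Pcsk2. Whether the licensing value depends on those cells was not tested.

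The last comparison was between ages within a genotype. In WT melanotroph-like cells, Mcm2 (-0.05), Ccnd2 (-0.10), Cdkn1a (0.07), Cdkn2a (-0.11) and Neat1 (-0.04) gave log2 ratios of 40 over 14 weeks near 0. In p25OE cells Mcm2 (0.17) and Cdkn1a (0.15) stayed near 0 as well, while Ccnd2 (-3.10) and Ccnd1 (-4.31) were lower and Sp8 (1.92), Cdkn2a (1.85), Tmprss6 (1.85) and Neat1 (1.02) higher at 40 weeks. Ccnd1 was also lower in WT, at -2.22. Isg15 gave 0.70 in WT and -1.59 in p25OE. The p25OE over WT log2 ratio at 40 weeks minus that at 14 weeks was -3.00 for Ccnd2, 2.17 for Sp8, 0.22 for Mcm2 and -2.29 for Isg15, values that were not tested. The first 8 bases of the cell barcodes were shared at 97.8% between the 14-week libraries and at 99.9% between the 40-week libraries, but at 24.7% to 26.5% across ages, so age and the set of barcodes cannot be told apart. The single kit version in the labels does not account for 2 sets of barcodes, and a difference in kit between the ages would bear on every value across ages.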

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

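The tests on the share of melanotroph-like cells and on the licensing genes were chosen only after the results had been seen, and those on the interferon genes beforehand.

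Melanotroph-like cells made up 88.4% of the p25OE cells and 7.50% of the WT cells at 40 weeks. The filters on detected genes and mitochondrial UMIs are argued against. Over all deposited barcodes Gh and Prl together took a 32.5-fold lower share of the UMIs in p25OE than in WT. A filter on barcodes before deposit, which is not stated, is not addressed by that value. Free Pomc RNA in other cells would dilute Pax7 per UMI, but Pax7 was 1.22-fold higher in the p25OE melanotroph-like cells (1.10 to 1.34). An even loss of all anterior-lobe cells cannot be told apart. Relative to somatotroph-like cells, corticotroph-like ones were at 0.361 of WT (0.171 to 0.691), where the WT libraries alone differ 1.79-fold. Gonadotroph-like ones were 7.05-fold higher (3.91 to 12.4), which goes against it. These values rest on 11 and 22 p25OE cells of 1 library, with intervals that hold counting error only. Per somatotroph-like cell, gonadotroph-like cells were already more frequent in p25OE at 14 weeks (0.103, and 0.0453 in WT). Lactotroph-like cells, with 81 p25OE cells, were at 1.08 of WT (0.770 to 1.52), which by itself goes with an even loss. With at least 1000 genes per cell, p25OE held only 7 lactotroph-like cells and WT 1461. The somatotroph lineage then held 135 and 1462 cells. With doublets kept, p25OE held 31 lactotroph-like cells. The value of 1.08 thus depends on the setting and decides nothing. Thyrotroph-like and stem-like cells were at 0.387 (0.0454 to 1.49) and 0.461 (0.238 to 0.833). An expansion of melanotroph-like cells in p25OE mice, a dissection that kept mostly the intermediate lobe and a difference between animals stay open as well, all untested.

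In melanotroph-like cells the licensing genes around Mcm2 were higher in p25OE at both ages. Cells seen in G2 or mitosis are argued against as the whole source. Among cells with no UMI of the 10 cell cycle genes the median log2 ratio was still 0.95 at 40 weeks (0.80 to 1.36), the smaller of the 2 ages. These cells were chosen without thinning, and p25OE cells were the shallower ones at 14 weeks. Cells in G2 or mitosis whose UMIs were missed may therefore remain among them. S phase genes had medians of 1.08 at 14 weeks and 1.30 at 40 weeks in the same cells, so the test does not address cells in S phase. A shift of the whole library at 14 weeks is argued against as well, since macrophage-like cells gave 0.45 (0.26 to 0.74) beside 1.53. At 40 weeks they gave 0.97 (0.50 to 1.21) beside 1.11, which by itself goes with such a shift. Gene by gene the melanotroph-like ratios lay above those of somatotroph-like, lactotroph-like and macrophage-like cells by medians of 0.57, 0.72 and 0.37. Of the shared genes, 14 of 17, 14 of 20 and 11 of 16 were higher in melanotroph-like cells. The lactotroph-like median over its shared genes was 0.89, beside 0.94 in melanotroph-like cells. Under equal ratios 1, 0 and 17 of 2000 redraws, which hold counting error only, reached the median differences. For somatotroph-like and lactotroph-like cells the redraws argue against 1 equal shift of the whole library as the whole source. For macrophage-like cells they cannot decide, since 0.37 lies close to 0.31, the upper end of what equal ratios give. Plain CPM shifts macrophage-like ratios by 0.45 and melanotroph-like ones by 0.38. This takes the difference of 0.37 to just under that end, as computed with the reported scaling. A smaller shift shared by all classes stays open (32.1% of those p25OE macrophage-like cells held Pcsk2, from a source not tested), and so does an effect of p25 on origin licensing, the difference that the design names, which is untested.

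Interferon response genes were higher in the p25OE library at 14 weeks in melanotroph-like (median log2 1.29), somatotroph-like (1.27), lactotroph-like (1.98) and macrophage-like cells (0.69). For free RNA of macrophages, the 7 macrophage markers had a median log2 ratio of 0.33 (0.13 to 0.51) in melanotroph-like cells. This lay below the lower bound of 1.15 of the interferon list, the outcome set beforehand as going against that source. The test cannot decide, however, since interferon genes were themselves 0.69 higher in macrophage-like cells. Free macrophage RNA would carry that rise as well, which the markers do not measure. Damaged cells with much mitochondrial RNA are argued against in melanotroph-like cells, where the list median with at most 10% mitochondrial UMIs was 1.36 (1.16 to 1.53). That value does not address the other classes, or damage without much mitochondrial RNA. An interferon response in the tissue of that library, whether or not it follows from p25, may be the source, and 1 library does not part genotype from infection or handling.

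A set of results stood out because p25OE over WT log2 ratios had opposite signs at the 2 ages, and the difference between ages was not tested. In all kept cells the haemoglobin median was 2.48 at 14 weeks and -13.88 at 40 weeks. The neutrophil genes Camp, Ngp, S100a8 and S100a9 gave 10.66, 9.08, 4.44 and 4.38 at 14 weeks. At 40 weeks they gave -10.77 (with a floor of 3 counts for the 0 UMIs in p25OE), -13.18, -7.13 and -7.58. Tshb, the thyrotropin gene, gave 0.77 and -9.63. The haemoglobin median was 5.84 and -5.75 in somatotroph-like cells, 4.88 and -6.83 in lactotroph-like cells, 5.57 and -12.63 in melanotroph-like cells and 3.24 and -8.78 in macrophage-like cells. Erythroid cells numbered 41 in WT at 40 weeks and 0, 1 and 0 in WT at 14 weeks and p25OE at 14 and 40 weeks. In melanotroph-like cells the Notch, Wnt and stem signalling median was 0.59 and -0.76, the gonadotropin gene Fshb gave 1.65 and -6.03, and the binding protein genes Igfbp5 and Igfbp7 gave 1.12 and 2.08 against -3.10 and -5.74. Free RNA of other cells limits these values.

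Barcodes outside the kept cells also differed between genotypes of an age. In the p25OE library at 14 weeks 43.6% of the barcodes had fewer than 500 genes and 27.5% had more than 20% mitochondrial UMIs, against 18.5% and 12.7% in WT. At 40 weeks 4.46% of the p25OE and 34.2% of the WT barcodes had fewer than 500 genes, and 0.997% and 0.158% had more than 20% mitochondrial UMIs. These differences were not tested.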

How the results depend on the processing

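Leaving out the top doublet scores, adding the proliferating cells, cells with no cell cycle UMI and single UMIs of Pcsk2 or Pax7 were chosen only after the results had been seen. Of 360 class shares under other settings 193 stayed within their interval and 167 moved, of 48 cycling shares 32 and 16, of 3468 gene ratios 2765 and 697, and of 2272 list medians 1766 and 499. The other 6 gene ratios and 7 list medians took the opposite sign of a reported value beyond 1.5-fold, while with reported values of any size 66 and 173 took the opposite sign. The melanotroph-like share stayed higher in p25OE at both ages under every setting run, and the licensing and S phase medians of melanotroph-like cells stayed above 0, from 0.95 to 1.74 and from 1.08 to 1.76. The cause of a difference was not tested unless given.

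Values below are log2 ratios of p25OE over WT or percent of cells, with the reported value in brackets. With list members of at least 100 UMIs, G2 and mitosis genes gave -0.070 [1.04] and -0.42 [0.997] in somatotroph-like, -0.22 [1.29] and -0.95 [1.22] in lactotroph-like and 3.06 [2.39] and 3.07 [2.51] in melanotroph-like cells at 14 and 40 weeks, -0.58 [3.03] in macrophage-like cells at 40 weeks, and licensing genes -0.10 [0.64] in lactotroph-like cells at 40 weeks; fewer members remain there. With at least 1000 genes per cell, Prl gave 2.62 [-5.43] and Rnaset2b 0.22 [-1.75] in somatotroph-like cells at 40 weeks, G2 and mitosis 2.77 in melanotroph-like cells at 14 weeks, and the melanotroph-like share was 28.8% [27.0%] in p25OE at 14 weeks and 8.81% [7.50%] in WT at 40 weeks. With doublets kept, Prl gave 2.52 and Rnaset2b 0.21 there. With each library clustered on its own, Cga gave 1.27 [-4.61] in somatotroph-like cells at 40 weeks, Pomc -0.24 [1.05] in lactotroph-like cells at 14 weeks, licensing genes -0.11 in lactotroph-like cells at 40 weeks and G2 and mitosis 2.77 in melanotroph-like cells at 14 weeks, with melanotroph-like shares of 24.1% (p25OE, 14 weeks), 8.14% (WT, 40 weeks) and 87.5% [88.4%] (p25OE, 40 weeks). Adding proliferating cells gave 3.77 and 3.70 for G2 and mitosis in melanotroph-like cells, by construction. Plain CPM gave 1.49 [1.11] for licensing and 2.89 for G2 and mitosis in melanotroph-like cells at 40 weeks, and cells with no cell cycle UMI 1.15 [1.53] for licensing at 14 weeks.

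The melanotroph-like share was 7.95% [8.82%], 21.2%, 5.00% and 86.8% (WT and p25OE at 14 weeks, WT and p25OE at 40 weeks) with at least 200 genes, 9.67% in WT at 14 weeks with at most 10% mitochondrial UMIs, 22.6% and 87.0% in p25OE at 14 and 40 weeks at resolution 0.5, 87.4% at 40 weeks at resolution 2 and 89.4% without the top doublet scores. Cells with a UMI of Pcsk2 took 8.12%, 20.4%, 14.0% and 78.2%, and of Pax7 1.43%, 5.23%, 0.911% and 13.8%. Cycling cells took 0.927% [0.385%], 8.13% [2.24%], 0.416% [0.190%] and 28.7% [5.79%] without thinning, 0.619%, 2.97% and 8.62% in WT and p25OE at 14 weeks and p25OE at 40 weeks when thinned to 2000 UMIs, and 0.231%, 1.46% and 3.74% with 3 genes needed; deeper cells show more genes by construction.

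Other scalings shift all ratios. Plain CPM does so by 0.27 and 0.53 in all kept cells, 0.21 and 0.38 in melanotroph-like cells at 14 and 40 weeks, and 0.44 and 0.45 in somatotroph-like and macrophage-like cells at 40 weeks. Totals without hormones shift them by 0.13 and 0.15 in all kept cells and 0.13 and 0.17 in lactotroph-like and macrophage-like cells at 40 weeks, and TMM by -0.13 in lactotroph-like cells at 14 weeks. With 7, 13, 31 and 16 lactotroph-like p25OE cells at 40 weeks (at least 1000 genes, at most 10% mitochondrial UMIs, doublets kept, top doublet scores out), no 40-week value could be computed for that class. Depth also limits the somatotroph-like class at 40 weeks, with 72 p25OE cells.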

Other observations

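The test that parts cells by Ccnd2 was chosen only after the result had been seen, and the tests on chromosomes and on the share of the 40-week difference beforehand.

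Many p25OE melanotroph-like cells held little Pomc. Cells with under 5% of their UMIs from Pomc numbered 458 of 2070 (22.1%) in p25OE and 11 of 580 (1.90%) in WT at 14 weeks, and 2620 of 6826 (38.4%) and 11 of 594 (1.85%) at 40 weeks. In the same class Hk2, which encodes a hexokinase, gave log2 ratios of -0.44 at 14 weeks (interval includes 0) and 3.02 at 40 weeks, and Atf4, a factor of the stress response, 0.08 and 1.10. One cluster shared by p25OE cells of both ages had few UMIs per cell (medians of 4457 and 1994), more mitochondrial UMIs (11.4% and 8.70%) and much of the nuclear RNA Malat1 (42086 and 51301 CPM, against 20176 and 19945 in the WT clusters of 14 and 40 weeks). A cluster of 348 p25OE cells and 34 WT cells at 14 weeks had fewer UMIs still (a p25OE median of 1650) and little Malat1 (1776 CPM).

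Single genes stood apart in other classes. In lactotroph-like cells Oxt, the oxytocin gene, lay at 4.37 scaled CPM in WT and 103 in p25OE at 14 weeks, while p25OE had 0 UMIs at 40 weeks. It leads a cluster of 181 p25OE and 8 WT cells at 14 weeks with few UMIs per cell, and Mbp and Stmn2, genes of nervous tissue, are among that cluster's leading genes. Lars2, a mitochondrial tRNA ligase gene, was 4.42-fold higher in p25OE at 14 weeks, and 5.28-fold in somatotroph-like cells. It too is among the leading genes of that low-UMI lactotroph-like cluster, beside Gm42418, AY036118 and mt-Nd4l, so the value may not reflect regulation of the gene. In somatotroph-like cells at 40 weeks the metallothionein gene Mt2, Sbno2 and Zfp36 gave log2 ratios of 3.39, 3.71 and 3.25.

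Whole chromosomes gained or lost in most p25OE melanotroph-like cells could raise or lower many genes together. At 40 weeks the farthest chromosome, 8, lay 0.12 from the median of chromosomes on the log2 scale, against the 0.3 asked for, so a gain or loss in most cells is argued against. In the cluster with few UMIs the X chromosome lay at -0.33 at 14 weeks, beyond 0.3, and at -0.29 at 40 weeks. The source of that was not tested, nor were gains or losses in a few cells.

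A further hypothesis is that the p25OE library at 14 weeks holds cells that already carry the 40-week profile beside cells that do not. The first test asked for under 0.25 of the 40-week log2 difference in the cluster shared with WT, over the 16 genes far apart at both ages. The median share was 0.80, beside 0.85 in the p25OE cluster with few UMIs, a result on the side against the hypothesis. It decides nothing, since the 16 genes were picked by their ratios in the whole class, at 14 weeks too. Most cells of the class at 14 weeks lie in the shared cluster, so a high share was largely built in. The bound was also ill chosen, because a sum over mixed cells keeps most of a log2 difference when most of the cells carry it. Of the 1074 p25OE cells of the shared cluster, 79.1% had no UMI of Ccnd2 after thinning to 5000 UMIs, against 14.2% of 500 WT cells.

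Within that cluster, p25OE cells without Ccnd2 (849) were therefore set against those with 2 or more of its UMIs (125). The 16 genes, of which Ccnd2 is none, differed by a median log2 of 1.12 (1.05 to 1.45), in the direction of the p25OE profile, against 0.20 (0.067 to 0.47) between the same kinds of WT cells. In WT, Pyy had 0 UMIs in both kinds of cells and Mcm3 in those without Ccnd2, and over the other 14 genes the medians were 1.12 and 0.20. Cells without Ccnd2 had 70.1 CPM of Mcm3 and 111 of Cdkn1a, and those with it 14.6 and 28.4. Neat1 stood at 310 and 65.0 CPM, and Gabra2, lower in p25OE, at 22.3 and 49.5. The p25OE cells with Ccnd2 were not like WT: WT cells with 2 or more of its UMIs had 1.92 CPM of Mcm3, 8.85 of Cdkn1a and 23.9 of Neat1, and the median distance over the 16 genes was 1.24 (1.001 to 1.49). With 4 or more UMIs of Ccnd2 it was 0.67 (0.53 to 1.07), on 34 p25OE and 117 WT cells. Cells with least Ccnd2 may thus be those with most of the licensing genes and Cdkn1a, but 2 states side by side cannot be told apart from a graded difference, since 2 UMIs of Ccnd2 part the cells imperfectly.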
